A study of Shewanella decolorationis S12 with 6 samples.

How the data were processed

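Total RNA of 6 samples, 3 of normal cells at 0.5 h and 3 of filamentous cells at 8 h with 0.5 mmol/L amaranth, was freed of DNA with DNase and of ribosomal RNA with a removal kit and sequenced on an Illumina instrument, per the labels and the series description. The submitters' processing notes name TopHat2 2.0.11, SAMtools 0.1.18.0, Cufflinks 2.0.0 and Cuffdiff, without saying how each was used. The genome build, annotation, strand setting and treatment of reads with several matches are not given in the sources used here.

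A single table was used, in the layout of a comparison of gene expression. Per the file headers, the authors deposited for each gene an FPKM value, a number of fragments scaled by gene length and sequencing depth, in each group. The authors also deposited the log2 ratio of filamentous over normal cells, an adjusted p-value (false discovery rate) and a yes or no call. No status column was given, so untested genes could not be told from tested ones except where both groups were at 0. The log2 ratio equals that of the deposited FPKM values within 1.2e-05 and has no pseudocount. It was infinite where 1 group was at 0. Of these 25 genes, 23 were shorter than 200 bp or shared their position with another gene, and no fold was computed for them. In that set, 2 genes had an adjusted p under 0.05. The lowest adjusted p, 0.000222, was shared by 1495 genes, so smaller values could not be ranked. The yes calls were genes with an adjusted p under 0.05 and an absolute log2 ratio of at least 1, with 1 exception of 0.98; the 2 genes past both limits and not called were at 0 in a group. The 206 empty lines at the end of the table were left out.

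Positions were given on contigs of a draft assembly, and contigs are named here by their number. Starts count from 0 in the table and were converted to count from 1. In all, 882 genes (20.9%) shared their listed position with another gene, so their own ends are not known. Of the 3337 genes with their own position, 99.3% had a length divisible by 3, so these are coding lengths. FPKM times length over these genes came to 1360961 fragments per 1000000 sequenced at 0.5 h and 788504 at 8 h. The first exceeds 1000000, so the values are not fragments divided by the listed length and by depth alone. A further scaling between groups or a shortened effective length of genes would both give this, and neither is stated in the sources used here. The median FPKM was 69.7 and 71.0. Depth per library is unknown, since the table holds 1 value per group, and no counting interval or limit was computed.

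Before the data were examined, 26 gene lists, the call by adjusted p, and the alternatives of a stricter adjusted p, a 2-fold limit, a pseudocount, centring and equal sums for the count of genes were fixed, and the others named below were added later. The lists could not be tested, because the table has no gene names and 0 identifiers matched. By the fixed rule for tables without names, the text names at most 2 identifiers per direction: those with the largest change among genes with an adjusted p under 0.05, FPKM above 0 in both groups and at least 10 in 1 or both; the 5 genes with the highest mean are given by position. The direction is 8 h over 0.5 h throughout, and genes are said to have risen or fallen where the authors' adjusted p was under 0.05.

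The description by position was chosen after the table had been seen. Runs of adjacent genes in the authors' significant list with the same direction were counted from 5 genes and described from 7 genes. The count was compared with 10000 shuffles of the calls over all gene positions. Adjacent genes above 0 in both groups were grouped by the distance between their listed positions and their log2 ratios correlated, with 10000 permutations and 2000 bootstrap resamples of pairs. Genes were divided into 10 classes by the mean of their log2 FPKM in both groups. Contigs with at least 20 genes were tested by Fisher's exact test and by all circular shifts of the calls along the table, where the share of shifts with at least as many calls, or for fewer calls with at most as many, was doubled. Gene length was compared with the log2 ratio over 3292 genes with their own position (Spearman's rho -0.03, permutation p = 0.103).

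The procedures were tested on simulated data made from the 4157 genes above 0 in both groups. A constant of 15 FPKM added to the second group was recovered as 14.7 on average over 20 simulations, with a ratio of the rises of the second over the lowest class of 1.02. Where weakly expressed genes instead rose 2-fold, this ratio was 2.03. No scaling between the groups and no fall of highly expressed genes was simulated. The simulations therefore do not show that a constant is recovered where these occur. Shuffled calls gave 3 runs of at least 5 genes, and 42 after 40 runs had been planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were a stricter adjusted p, a 2-fold limit, a pseudocount of 1, centring on the median, equal sums in both groups, a minimum mean of 10 FPKM, leaving out shared positions and taking a constant off the values at 8 h. Time, dye exposure and cell shape differ together between the groups and cannot be separated, as no dye-free group is among the samples.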

Results

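Shewanella decolorationis S12 is a dye-decolourising gammaproteobacterium that respires without oxygen on extracellular electron acceptors. It was grown under anaerobic conditions in a lactate medium containing 0.5 mmol/L amaranth, a red azo dye. Messenger RNA was sequenced from 3 libraries of cells of normal shape, taken after 0.5 h with the dye, and from 3 libraries of filamentous cells, taken after 8 h. Filamentous cells have grown long without dividing. The deposited table gives 1 FPKM value per gene and group for 4219 genes on 69 contigs of a draft genome, with no value per library, so the number of reads behind a value and the spread between libraries are not known. Of these genes, 4157 were above 0 in both groups, 37 were listed at 0 in both, 23 were listed at 0 only at 0.5 h and 2 only at 8 h. The table identifies genes by locus tag and position and does not pair them with gene names, so gene functions are not described here and the 26 pathway lists fixed in advance had 0 matching members.

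The main comparison asks which transcripts differed between filamentous cells after 8 h with the dye and normal cells after 0.5 h. In the authors' deposited table, 2487 genes (58.9% of those listed) had an adjusted p under 0.05. Of these, 1249 rose and 1238 fell at 8 h. The authors' own list of significant genes, which also asks for an approximately 2-fold change, holds 1620 genes, of which 891 rose and 729 fell. Among these, the median log2 ratio was 1.62 for genes that rose and -1.49 for genes that fell. A change of at least 4-fold was listed for 271 genes that rose and 159 that fell, and a change of at least 16-fold for 32 and 5 genes, respectively.

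The largest rise was that of SHD_1876 (contig 63, positions 51372 to 51701), from 3.51 FPKM at 0.5 h to 1013 FPKM at 8 h, a log2 ratio of 8.17 with an adjusted p of 0.000427 in the authors' deposited table. The gene before it, SHD_1875 (contig 63, positions 49463 to 51193), rose from 8.40 to 1201 FPKM in the authors' deposited table, a log2 ratio of 7.16. In the authors' deposited table, the adjacent gene at positions 48027 to 49415 rose with this pair, from 6.08 to 568 FPKM, a log2 ratio of 6.55, and the gene beside it, at positions 46587 to 47747, rose from 16.2 to 55.1 FPKM, a log2 ratio of 1.77. With a further gene whose listed position is shared, these genes form a run of 5 (positions 43745 to 51701). Their median log2 ratio was 6.55, the highest of the 46 runs of at least 5 genes described below. Single genes of this run ranged from 1.14 to 8.17. The next gene on the other side, at positions 52195 to 52926, was listed at 56.7 and 30.5 FPKM in the authors' deposited table. The largest fall was that of SHD_1993 (contig 65, positions 39375 to 39824), from 775 to 17.1 FPKM, a log2 ratio of -5.50 with an adjusted p of 0.000222 in the authors' deposited table. Its neighbours did not share this fall: in the authors' deposited table, the gene before it was at 13.1 and 27.7 FPKM and the gene after it at 13.2 and 15.8 FPKM. With a constant of 13.2 FPKM, the median rise of the most weakly expressed genes, taken off the values at 8 h, the log2 ratio of SHD_1993 was -7.65. SHD_2863 (contig 71, positions 27493 to 28941) fell from 8572 to 275 FPKM in the authors' deposited table, a log2 ratio of -4.96. The genes on either side of it had log2 ratios of -0.65 and 0.62 in the authors' deposited table.

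The 5 genes with the highest mean level all fell in the authors' deposited table. The highest in FPKM, a feature of 124 bp that begins at position 1 of contig 44, fell from 252437 to 84803 FPKM in the authors' deposited table, a log2 ratio of -1.57, and made up 10.3% of the summed FPKM at 0.5 h and 6.46% at 8 h. A shortened effective length, left open above, would raise the FPKM of so short a feature, so its rank and share are uncertain. A gene of 267 bp on contig 61 (positions 48400 to 48666) followed, at 84740 and 44743 FPKM in the authors' deposited table, a log2 ratio of -0.92, or -0.03 with both groups at the same sum. The other 3 lie on contig 52 and had log2 ratios of -1.93, -1.53 and -1.68 in the authors' deposited table. The adjusted p of these genes in the authors' deposited table was at most 0.00300. The 100 most abundant genes of each group held 64.3% of the summed FPKM at 0.5 h and 48.9% at 8 h.

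The calls are those of the authors' comparison of 3 with 3 libraries, and nothing in the labels says that the libraries came from separate cultures, so the p-values may measure technical spread only. The deposited FPKM sum to 2442549 at 0.5 h and 1312318 at 8 h. When both groups were set to the same sum, every log2 ratio rose by 0.90. Of the 2487 genes, 417 changed from lower to higher, which left 1666 higher and 821 lower. The authors' adjusted p was kept, as it could not be computed again at this scaling, so the set of 2487 genes was fixed. The directions below refer to the authors' scaling.

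The direction of change followed the expression level of the genes. When the 4157 genes above 0 in both groups were divided into 10 classes of about equal size by their mean level over both groups, the median log2 ratio went down from class to class. In the lowest class it was 1.29 (95% bootstrap interval over genes 1.23 to 1.41), with median values of 9.42 FPKM at 0.5 h and 22.9 FPKM at 8 h. In the fifth class it was -0.06 (-0.15 to 0.04), and in the top class -1.11 (-1.24 to -0.98), with median values of 1343 and 904 FPKM. With both groups at the same sum the order of the classes is kept and the medians run from 2.19 to -0.22, with that of the top class alone below 0. With a constant of 13.2 FPKM taken off the values at 8 h, the medians of the lowest 3 classes were 0.11, 0.10 and -0.09 and that of the top class -1.14; the constant is the median rise of the lowest class, whose median is therefore set near 0. In the lowest 3 classes together, 502 of 1247 genes were in the authors' significant list as higher and 14 as lower. In the top 3 classes, 158 of 1247 were higher and 483 lower. With the constant taken off, 511 of the 891 genes listed as higher stayed at 2-fold or more. These intervals cover the spread between genes, which are not independent replicates, and not the spread between libraries.

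**Figure D1:**
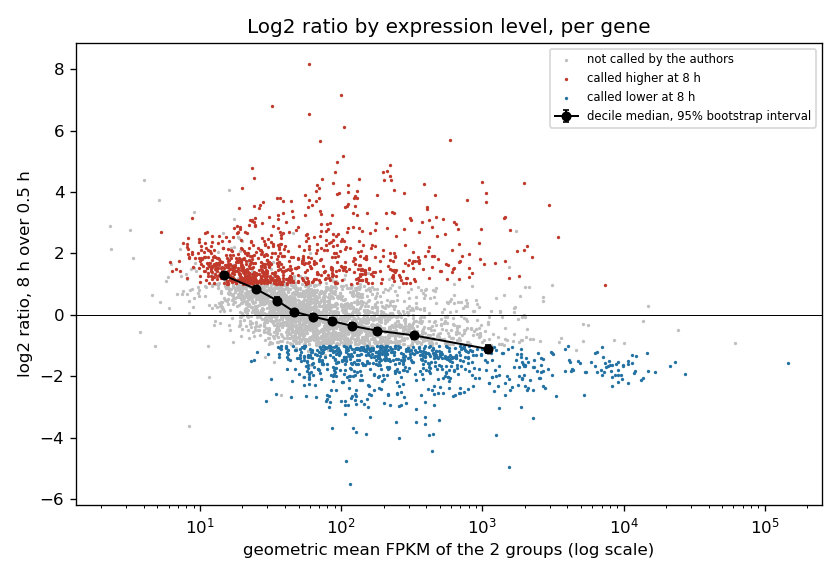
Each point is a gene; the x axis is the geometric mean of its FPKM in both groups on a log scale and the y axis the authors' log2 ratio of 8 h over 0.5 h. Black circles are the medians of 10 classes of genes by mean level with 95% bootstrap intervals; they go down from 1.29 in the lowest class to -1.11 in the top class, or from 2.19 to -0.22 with both groups at the same sum and from 0.11 to -1.14 with a constant of 13.2 FPKM taken off the values at 8 h.

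Genes that fell were grouped in the genome. FPKM values of a region are given as the median over its genes in each group, which can fall on different genes, so their ratio can differ from the median log2 ratio. A region of contig 52 (positions 1307 to 16446) holds 28 adjacent genes that all fell, with log2 ratios between -2.31 and -1.50 and a median of -1.83, a 3.55-fold decrease. These 28 genes were among the most abundant transcripts, with a median of 17943 FPKM at 0.5 h and 5041 FPKM at 8 h, and held 23.9% of the summed FPKM at 0.5 h against 12.6% at 8 h. On contig 60, 13 adjacent genes (positions 47840 to 58096) fell with a median log2 ratio of -2.53, from a median of 1651 to 282 FPKM. A second region of contig 60 with 9 genes (positions 67036 to 75553) had the lowest median of the described regions, -2.99, and fell from 439.9 to 55.2 FPKM. On contig 16, 11 adjacent genes (positions 865 to 16875) fell from a median of 11590 to 4409 FPKM, with a median log2 ratio of -1.52. Genes whose listed position is shared with another gene made up 5 of the 28 on contig 52. On contig 60 they made up 4 of 13 and 6 of 9, and on contig 16 they were 0 of 11. How reads were divided among genes with a shared position is not known, so their values may not be separate measurements.

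**Figure D2:**
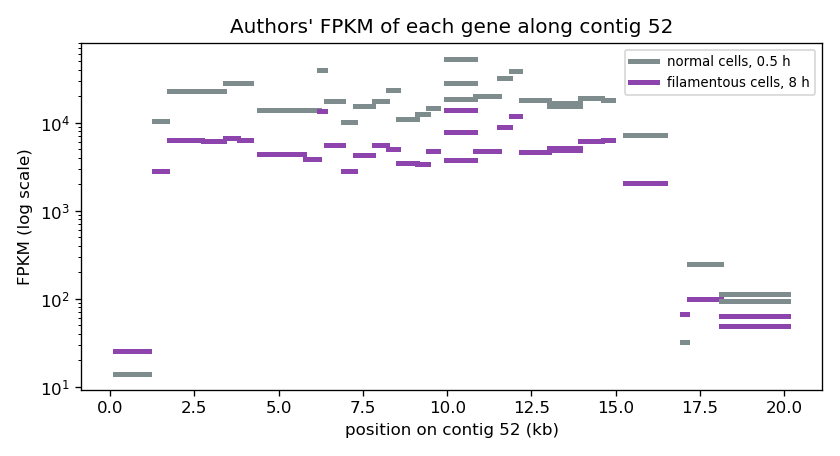
The x axis is the position on contig 52 in kb and the y axis the authors' FPKM on a log scale; each bar spans the listed position of a gene, in grey for normal cells at 0.5 h and in purple for filamentous cells at 8 h. The 28 genes between positions 1307 and 16446 stand far above the other 5 genes of the contig in both groups, each lower at 8 h, by log2 ratios of -2.31 to -1.50.

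The remaining regions of at least 7 adjacent genes that fell had medians between -2.54 and -1.88. A region of contig 24 (positions 19074 to 31217, 10 genes) fell from a median of 2168 to 528 FPKM, and a region of contig 50 (positions 57821 to 64823, 9 genes) from 4533 to 1251 FPKM. On contig 41, 8 genes (positions 1843 to 8343) fell from 849 to 189.6 FPKM. On contig 76, the longest contig, 7 genes at positions 5761 to 13040 fell from 1050.5 to 190.8 FPKM and 7 genes at positions 109667 to 116688 from 2407 to 517 FPKM. A listed position shared with another gene was held by 4 of the 10 genes on contig 24 and by 0 on contigs 50 and 41. In the 2 regions of contig 76 it was held by 2 and 4 of the 7 genes, respectively. The 102 genes of these 9 regions held 35.0% of the summed FPKM at 0.5 h and 18.1% at 8 h. With both groups at the same sum, 3 of the 9 regions had medians of less than 2-fold, those of contig 52 (-0.93), contig 24 (-0.98) and contig 16 (-0.63).

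Genes that rose were also grouped, in 10 regions of at least 7 adjacent genes with 80 genes in all. Most were weakly expressed at 0.5 h: together these genes held 0.191% of the summed FPKM at 0.5 h and 2.12% at 8 h. The largest rise was that of 7 genes on contig 47 (positions 10964 to 17298), with a median log2 ratio of 4.29 and a median level of 18.1 FPKM at 0.5 h and 384 FPKM at 8 h. Of these 7 genes, 4 share 1 listed position (10964 to 14949), and the median log2 ratio is the value of 1 of them. On contig 48, 11 adjacent genes (positions 5479 to 19153) rose with a median log2 ratio of 3.79 and a range of 1.15 to 4.67; the median level was 28.0 FPKM at 0.5 h and, on another gene, 151.7 FPKM at 8 h. On contig 69, 7 genes (positions 74390 to 81743) rose from 26.8 to 155.4 FPKM, and among them a gene of 441 bp at positions 75103 to 75543 rose from 81.0 to 4235 FPKM in the authors' deposited table. On contig 65, 8 genes (positions 22377 to 33322) rose from 8.22 to 59.4 FPKM, with log2 ratios between 2.12 and 3.07. Shared positions were listed for 6 of the 11 genes on contig 48, 4 of the 8 on contig 65 and 0 on contig 69.

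Contig 53 held 2 regions that rose, of 8 genes (positions 55273 to 63748) and 9 genes (positions 64627 to 74799), with median log2 ratios of 2.11 and 2.08. Contig 68 also held 2, of 9 genes (positions 200462 to 214866) and 7 genes (positions 243376 to 249525), with medians of 1.66 and 2.42. On contig 49, 7 genes (positions 36484 to 41457) rose by a median of 1.77, and on contig 66, 7 genes (positions 43920 to 51589) rose by a median of 1.48, from 94.1 to 262 FPKM. Shared positions were listed for 3 of the 8 and 4 of the 9 genes on contig 53. On contig 68 they were listed for 2 of the 9 and 4 of the 7 genes, and on contigs 49 and 66 for 2 and 0. The region of contig 68 with 9 genes rose from only 20.9 to 43.5 FPKM. After a constant of 13.2 FPKM was taken off the values at 8 h, 6 of its 9 genes stayed at 2-fold or more. In the regions of 7 genes on contigs 47 and 68, 6 of the 7 genes did so, and in the other described regions that rose all did.

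**Figure D3:**
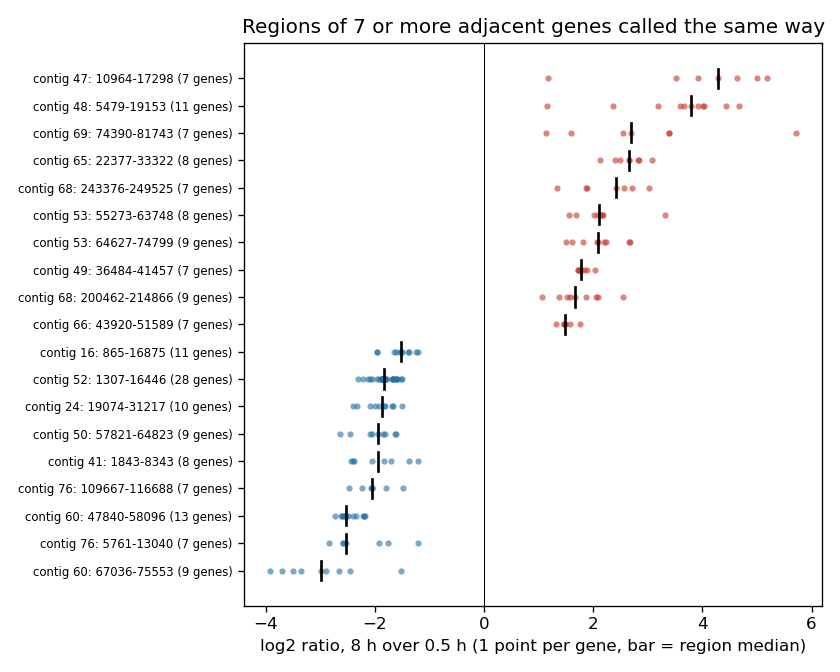
Each row is a region of 7 or more adjacent genes in the authors' significant list with the same direction, labelled by contig, positions and number of genes; the x axis is the log2 ratio of 8 h over 0.5 h, points are genes and black bars region medians. The 9 regions that fell have medians between -2.99 and -1.52 and the 10 that rose between 1.48 and 4.29.

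In all, 46 runs of at least 5 adjacent genes were in the authors' significant list with the same direction, 27 higher and 19 lower, and they held 328 genes (20.2% of the list). In 10000 shuffles of the genes over the positions, the mean was 1.83 runs and the highest 8, and the longest run was 11 genes against the 28 observed (one-sided permutation p = 0.0001, the smallest these shuffles can give). These shuffles moved each gene by itself, also those with a shared position, so the p-value is only against calls placed independently of neighbours. Without genes that share a listed position, 29 runs were found, for which no shuffles are given. When the 2-fold limit was applied again to all genes with an adjusted p under 0.05, there were 43 higher and 4 lower runs with both groups at the same sum, and 15 higher and 24 lower with the constant taken off. The log2 ratios of adjacent genes were correlated across genes, the more so the closer they lay. Pearson's r was 0.82 (95% bootstrap interval 0.78 to 0.86) and Spearman's rho 0.79 for 924 pairs separated by under 50 bp. Pearson's r was 0.88 for 482 overlapping pairs or pairs with a shared position, 0.48 for 692 pairs from 50 to under 100 bp, 0.30 for 904 pairs from 100 to under 200 bp and 0.20 for 748 pairs from 200 to under 400 bp. At 400 bp or more it was 0.04 (-0.07 to 0.16) for 352 pairs. When genes with a shared position were left out, so that genes on either side of them became neighbours, r at 400 bp or more was 0.15 (0.06 to 0.24, unadjusted permutation p = 0.0003) for 611 pairs. Two-sided permutation p-values, adjusted by the Benjamini-Hochberg method over the 6 distance classes, were 0.0001 for each class under 400 bp, the smallest the shuffles can give, and 0.459 at 400 bp or more. Genes are not independent replicates, so these values describe this table.

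**Figure D4:**
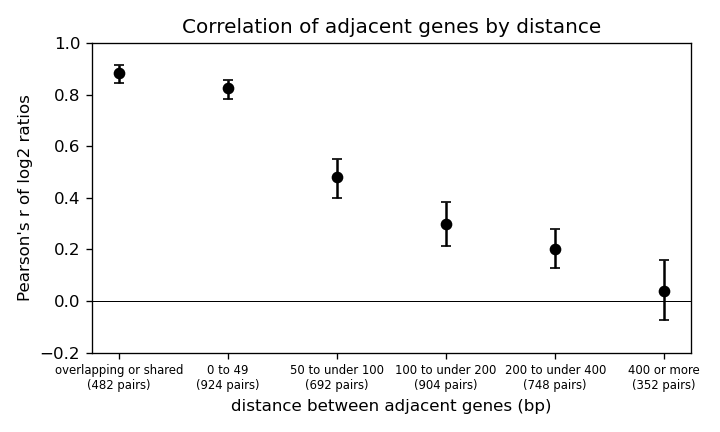
The x axis is the distance between adjacent genes in bp, with the number of pairs, and the y axis Pearson's r of their log2 ratios, with 95% bootstrap intervals over pairs. The correlation goes down from 0.88 for overlapping or shared positions and 0.82 under 50 bp to 0.04 at 400 bp or more.

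Among the 41 contigs with at least 20 genes, 3 held more genes that fell than the rest of the genome by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over 82 tests) on the authors' significant list. These were contig 52 (29 of 33 genes, 87.9% against 16.7% elsewhere, adjusted exact p = 8.03e-17), contig 60 (44 of 95 genes, 46.3%, adjusted exact p = 1.25e-09) and contig 41 (15 of 40 genes, 37.5%, adjusted exact p = 0.0232). They include the regions described above, of 28 genes on contig 52, 13 and 9 on contig 60 and 8 on contig 41. The exact test counts genes as independent although adjacent genes changed together, so its p-values are too small and restate these regions in part. By the same exact test, 5 of the 82 comparisons had fewer such genes than elsewhere. Genes that fell were fewer on contig 4 (1 of 75, adjusted exact p = 0.000473), contig 64 (0 of 39, adjusted exact p = 0.0161) and contig 72 (14 of 164, adjusted exact p = 0.0176). Genes that rose were fewer on contig 52 (0 of 33, adjusted exact p = 0.0161) and contig 56 (5 of 73, adjusted exact p = 0.0176). The calls were also shifted along the gene order in all 4219 ways, so that neighbours stayed together. As many genes that fell were found on contig 52 at 4 shifts and on contig 60 at 27 shifts, the unshifted order included, and at each of these the contig overlapped itself. The unadjusted p-values of 0.0019 and 0.0128 count these overlaps, so the adjusted threshold over 82 tests decides nothing for these 2 contigs. For contig 41, 200 shifts gave as many, of which 15 overlapped the contig itself (unadjusted exact p over all shifts 0.0948). Of the 5 comparisons with fewer genes, 4 had an unadjusted p under 0.05 under these shifts and 0 passed after adjustment (lowest adjusted p 0.797). No contig held more genes that rose than the rest by Fisher's exact test after adjustment.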

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

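The alternatives that take off a constant, leave out shared positions or set a minimum mean, and those for runs, correlations and contigs, were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per group and none per library; for the same reason leaving out libraries and other splits of the libraries were not run. Adjusting the p-values again, by Benjamini-Hochberg or Bonferroni, was not run because the table has no unadjusted p, a change of the status filter was not run because no status is given, and the list alternatives had no members. Of 2487 genes with an adjusted p under 0.05, a 2-fold limit left 1621 (730 lower), the same limit on log2(FPKM + 1) left 1585 (719 lower), and the constant taken off at 8 h with the 2-fold limit left 1461, of which 511 were higher (35.0% of calls, against 55.0% with the 2-fold limit alone) and 950 lower. With equal sums in both groups, 821 of the 2487 genes were lower and 67.0% higher. The authors' adjusted p was kept there and under centring, so the total of 2487 could not change. The 46 runs became 84 without the 2-fold limit and 29 without shared positions, where fewer genes can form a run. With the 2-fold limit applied again there were 39 with the constant taken off, 15 higher and 24 lower, and 47 with equal sums, 43 higher and 4 lower. The 39 runs were counted from 511 higher and 965 lower genes, a lower count that differs from the 950 above. Under circular shifts, adjusted over 82 tests, the counts of 3 contigs with more genes that fell and of 5 comparisons with fewer genes that fell or rose were both 0, with 2 and 4 at an unadjusted p under 0.05. The smallest p a shift can give is 0.000474, or 0.0389 when multiplied by the 82 tests, and is reached only if no neighbouring shift gives as many. For contigs 52 and 60, the 4 and 27 such shifts all overlap the contig itself. Their adjusted p under circular shifts was 0.156 and 0.525, so this test decides nothing for or against these 2 contigs. In the other alternatives these counts stayed within 1.5 times, and the correlation under 50 bp stayed between 0.79 and 0.82. The log2 ratio of SHD_1993 went from -5.50 to -7.65 with the constant taken off, because its value at 8 h is close to that constant. Because depth is unknown, no limit of detection can be given for genes near the lowest values.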

Other observations

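All tests in this part were chosen after the table had been seen. Smaller groups of genes outside the regions described above also moved strongly. On contig 76, 5 adjacent genes (positions 943746 to 950803) fell with a median log2 ratio of -3.88, with median levels over these genes of 1040.5 FPKM at 0.5 h and 73.8 FPKM at 8 h. On contig 67, 5 genes (positions 106776 to 110371) rose by a median of 4.38, from 46.7 to 980 FPKM, and 6 genes at positions 93835 to 102382 by 3.47, from 33.8 to 435 FPKM. All 5 genes of the first group and 0 of the second share their listed position with another gene. On contig 37, 5 genes (positions 3684 to 11169) rose by a median of 4.12, from 5.10 to 83.2 FPKM, while 6 genes at positions 16234 to 23215 fell by a median of 1.65 on the log2 scale. Shared positions were listed for 2 of these 5 and 3 of these 6 genes. On contig 39, 5 genes (positions 3631 to 8877) rose almost equally, with log2 ratios between 1.41 and 1.51. Of these 5 genes, 3 share their listed position with another gene, so their values may not be separate measurements.

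Weakly expressed genes had higher values at 8 h as a class, by 13.2 FPKM (95% bootstrap interval 12.4 to 13.8) in the lowest class and 14.5 FPKM in the second, a ratio of 1.10 (0.99 to 1.23), although the levels at 0.5 h differed by 1.99 times. The median difference was 11.5 FPKM in the third class, 3.32 (0.88 to 5.61) in the fourth and -2.41 in the fifth, so a constant alone does not give the classes above the third. An additive background at 8 h, for example from residual DNA, may account for the rise in the lowest classes, as a hypothesis; a broad rise that shrinks with level would look the same and stays open, since the table has no intergenic values. One scaling factor between the groups as the only cause is argued against, because the lowest and the fifth class differed by 1.35 (1.24 to 1.49) in log2 ratio. A scaling factor acting together with a constant was not tested and stays open. The next values hold only if the constant were background and no scaling factor separated the groups. The constant would then make up 5.62% of the signal of genes with their own position at 8 h. Of the 891 genes that the authors list as higher, 380 (42.6%) would drop below 2-fold, 333 of them in the lowest 3 classes.

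The lower values of highly expressed genes were looked at separately. The class medians went down without a break over all 10 classes, however, and no test here tells 2 patterns from 1. With the constant taken off, the sixth and the top class still differed by 0.66 (0.52 to 0.87) in median log2 ratio. With the constant left in, the difference was 0.91 (0.75 to 1.09). Neither this constant alone nor one scaling factor between the groups alone gives this part. A constant and a scaling factor together were not tested and stay open. A change in the cells between 0.5 h and 8 h stays open and was not tested, as does any difference in growth phase, which goes with time in this design.

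Adjacent genes changed together. Reads split between overlapping genes are argued against, since r under 50 bp was 0.81 (0.75 to 0.85) among genes with their own position, against 0.15 (0.06 to 0.24) at 400 bp or more. A shared expression level is also argued against, since r was 0.81 (0.76 to 0.84) after the class medians were taken off. Transcription of close genes as one unit is a candidate explanation, as a hypothesis from the same data; strand, which would test it, is not in the table.

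On contig 76, the log2 ratio went up with position over 856 genes (Spearman's rho 0.12, Pearson's r 0.12, p = 0.0129 by circular shifts), and rho was 0.04 (p = 0.371) after the class medians were taken off.

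Among the 23 genes listed at 0 only at 0.5 h, the highest value at 8 h was 7027 FPKM, and 2 genes were listed at 0 only at 8 h. Of these 25 genes, 23 were shorter than 200 bp or shared their position with another gene, and 2 had an adjusted p under 0.05 in the authors' deposited table.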
